A study of Homo sapiens with 6 samples.

How the data were processed

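Poly(A) RNA was measured by bulk sequencing in 6 human libraries, 3 from induced pluripotent stem cells (hiPSC) and 3 from dental organoids derived from hiPSC at week 5, all labelled with the cell line WTC0011. Per the labels' protocols, messenger RNA was selected with oligo(dT) beads, fragmented and reverse transcribed with random primers, and the amplified products were made into circular single-stranded DNA libraries. Whether strand was kept is not stated, so reads of overlapping genes on opposite strands may not have been told apart.

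The values deposited by the authors are TPM (transcripts scaled to a fixed total per library), per the file headers, with 1 file per library and no pooling of replicates. HISAT2 2.21 is listed in the submitters' processing notes, with no role given. The genome build, annotation, counting tool and filters are not given in the sources used here. Each library listed the same 17431 genes by Entrez Gene number and symbol, and the values summed to 1000000. TPM keeps no depth, so no counting error could be computed, and a value of 0 may be a failed estimate. Because TPM fixes the total, a rise of many genes lowers the share left for others, and 2 further scalings were therefore run. Of the listed genes, 17386 matched the gene table of the GRCh38.p14 assembly by gene number; this table was used for gene types and chromosome only. Y-linked genes and XIST, 15 in all, were left out, which left 17416 genes.

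Genes with at least 1 TPM in at least 3 libraries were kept (13014), and log2(TPM + 1) was tested with limma 3.58.1 in R 4.3.3, with an intensity trend, group as the only term, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes. No fold is given for genes listed at 0 in every hiPSC library. A gene under 1 TPM in every library of a group was tested only by reaching 1 TPM in all 3 of the other group. Its direction then follows from the filter, as for the tested HOX genes, STMN2, KRT17, HES4, CXCR4, TTR and CD68. All adjusted p-values of genes come from limma, and those of lists from camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 34 lists, unless another test is named. Camera compares a list with all other tested genes. The spread within a group was the root mean square log2 difference of each library from its group mean. It was compared by a two-sided permutation test over all splits of the libraries. The distances of a group share 1 mean, which was not recomputed for each split, so this p is approximate.

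The samples' groups, the tests, the 34 lists, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule named 24 landmark genes whatever their result, of which 19 were analysed and 12 tested. The other 5 were not among the listed genes under their symbols. Some genes that the rule names are not reported here. It also named the 8 largest rises and the 8 largest falls among protein-coding genes past the threshold whose groups did not overlap and whose higher mean was at least 50 TPM, leaving out XIST, Y-linked and mitochondrially encoded genes. From each list it named up to 4 members: the 2 largest rises and the 2 largest falls past the threshold with a higher mean of at least 5 TPM, or, where fewer than 2 passed, the most abundant members. Genes named outside the rule are said to have been chosen after their values were seen.

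The alternatives were the replicate number as a block, quantile normalization, a scaling factor per library (a trimmed mean of log ratios on the deposited TPM, trimming 30% of ratios and 5% of levels at each end), limma without the intensity trend, limma with array weights, pseudocounts of 0.1 and 0.01, no filter, a filter of 5 TPM, a fold change of 2 tested in the model, an estimated correlation between genes, fry, and each library left out in turn. A correction for transcript GC content and length, taken from the longest protein-coding transcript of each gene in a GENCODE annotation (97.7% of tested genes matched), the scaling factor for the list tests and 5 further lists were added after seeing the data. The steps were tested on simulated data with the 13014 genes of this comparison and 5 draws of 200 changed genes. They recovered 71.2% of the genes changed by 0.5 on the log2 scale, 96.8% of those changed by 1, 99.2% of those changed by 2 and 100% of those changed by 3, and 4.47% of the calls were unchanged genes. A list shifted by 0.5 was called, and 0 of the other lists were. Genes were drawn independently there, whereas estimated correlations within the real lists reached 0.95. The simulation therefore does not show how often a list of correlated genes is called without a change. Its changes went in both directions, with no shift of all genes and none that varied with level. The rates of recovery and of false calls need not hold for the 4869 genes called in the real data.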

Results

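Bulk RNA was profiled in human induced pluripotent stem cells (hiPSC) of the line labelled WTC0011 and in dental organoids derived from hiPSC and sampled at week 5, with 3 libraries in each group. Every library listed 17431 genes in TPM (transcripts scaled to a fixed total) that summed to 1000000, so sequencing depth is unknown and no counting interval is given. Between 12545 and 12647 genes reached 1 TPM in the hiPSC libraries, and between 13052 and 13178 did so in the organoid libraries. Spearman correlations across the 13014 genes tested were 0.996 to 0.997 within hiPSC, 0.995 to 0.997 within the organoid group and 0.982 to 0.985 between the groups. Genes are not independent replicates. The root mean square log2 difference of a library from the farthest of its own group was at most 0.207, and that from the nearest library of the other group was at least 0.365. Distance to the group mean was 0.101 ± 0.00568 in hiPSC and 0.107 ± 0.0113 in the organoid (log2 units, mean ± SD, n = 3). A two-sided permutation test gave an approximate p = 0.6, where 0.1 is the smallest p this design allows. Nothing in the labels says that the replicates are separate cultures, so the p-values of genes measure the spread between these samples, which may be technical. Camera p-values with the preset correlation treat genes as the units compared. They do not use the correlation of a list's genes in these libraries.

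The single comparison of the design asks how expression in the week 5 organoid differed from that in hiPSC. Metallothionein genes made up 5 of the 8 largest rises among genes with a higher mean of at least 50 TPM. Most tested genes of the stress-response, matrix, basement membrane and HOX lists were higher in the organoid on the deposited TPM. For the 7 tested HOX genes, listed at 0 in every hiPSC library, this follows from the filter. Cell cycle genes were lower as a list (camera adjusted p = 1.96e-06), although 23 of 31 did not pass, 7 fell and 1 rose. With an estimated correlation none of these list calls held (adjusted p = 0.665 for cell cycle genes, and at least 0.559 for every list). That version of camera estimates the correlation from the 6 libraries and leaves few degrees of freedom. It can miss real shifts, so a list not called there is not shown to be unchanged. POU5F1, LIN28A and SOX2, by contrast, were read in the organoid at 0.827, 1.04 and 1.01 times their hiPSC levels. Of 13014 genes tested with limma, 4869 (37.4%) changed at an adjusted p under 0.05, 4004 higher and 865 lower in the organoid. The 3 libraries of one group lay entirely above those of the other for 6357 genes (48.8%, against 10% by chance). The median absolute log2 fold change over all tested genes was 0.17, and 273 genes changed at least 2-fold, of which 272 were higher (203 of 209 after the scaling factor). The single gene that fell 2-fold or more was the histone gene H2AC13, named after its values were seen, at 2.97 ± 1.28 TPM in hiPSC and 1.01 ± 0.882 TPM in the organoid (adjusted p = 0.0186). Near-identical histone copies make that value uncertain. The split between higher and lower genes depended on scaling: the median log2 fold change of all tested genes was 0.11 on the deposited TPM, -0.03 after a scaling factor per library and -0.03 after quantile normalization. The changed genes were 82.2% higher on the deposited TPM, 46.4% higher after the scaling factor (2436 higher and 2810 lower) and 46.2% higher after quantile normalization (2085 higher and 2432 lower). Of the 4869 genes, 1751 were higher and 818 lower under all 3 scalings.

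Metallothioneins, small cysteine-rich proteins that bind zinc and copper, made up 5 of the 8 largest rises among protein-coding genes with a higher mean of at least 50 TPM. MT1H rose from 2.78 ± 1.28 to 137 ± 8.82 TPM (log2 fold change 5.25, SE 0.19, adjusted p = 2.77e-09). MT1G rose from 13.4 ± 3.72 to 334 ± 12.4 TPM, MT1E from 2.56 ± 0.836 to 78.9 ± 7.66 TPM, MT2A from 17.5 ± 1.47 to 160.4 ± 34.4 TPM and MT1F from 14.6 ± 3.01 to 103 ± 7.72 TPM. These paralogs are close in sequence, so the share of each is less certain than the rise of the family. GDF15, a secreted stress-induced cytokine, rose from 3.45 ± 0.652 to 82.6 ± 2.38 TPM (log2 fold change 4.24, SE 0.10, adjusted p = 1.11e-10). TXNIP, an inhibitor of thioredoxin, rose from 12 ± 0.878 to 98.3 ± 6.38 TPM, and the histone gene H2AC6 from 15.5 ± 2.17 to 91.0 ± 4.88 TPM. The falls were smaller. FGFBP3, a fibroblast growth factor binding protein, fell from 93.1 ± 0.415 to 47.4 ± 0.548 TPM (log2 fold change -0.96, SE 0.06, adjusted p = 1.78e-07), and the zinc importer gene SLC39A10 from 62.3 ± 3.96 to 32.4 ± 2.92 TPM (-0.92). HMGCS1, an enzyme of cholesterol synthesis, fell from 153 ± 7.09 to 97.4 ± 6.37 TPM (-0.65), and FABP5, a fatty acid binding protein, from 756 ± 98.7 to 481 ± 27.2 TPM (-0.65). RPL36AL, ABRACL, CENPX and HNRNPA2B1 fell by 0.63, fell by 0.59, fell by 0.57 and fell by 0.56 on the log2 scale. All 16 of these genes kept their direction and their call under both other scalings.

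The pluripotency list moved in both directions. POU5F1, which encodes the core factor OCT4, fell from 2687 ± 135 to 2221 ± 68.8 TPM (log2 fold change -0.27, SE 0.06, adjusted p = 0.00509). LIN28A was at 962 ± 36.4 TPM in hiPSC and 999.7 ± 25.6 TPM in the organoid (adjusted p = 0.479), and SOX2 at 189 ± 8.99 and 190.1 ± 3.70 TPM (adjusted p = 0.883). NANOG rose from 74.4 ± 2.17 to 84.0 ± 1.99 TPM (0.17, adjusted p = 0.0313), a call lost after the scaling factor (0.03) and after quantile normalization (0.12). Of 28 tested members, 5 rose, 7 fell and 16 did not pass; 6 and 7 passed when adjusted over the list alone. PODXL, a surface sialomucin, rose from 295 to 415 TPM and UTF1 from 9.14 to 14.5 TPM, whereas the NODAL antagonist genes LEFTY1 and LEFTY2 fell from 35.7 to 24.98 TPM and from 18.2 to 11.6 TPM. The list was not called by camera (adjusted p = 0.0613, lower than other genes), but was called as lower after the scaling factor (adjusted p = 0.0304), where 2 members were higher and 11 lower. After quantile normalization it was not called (adjusted p = 0.832), with 5 members higher and 7 lower. It was called as lower without hiPSC replicate 1 (adjusted p = 0.0493) and without organoid replicate 3 (adjusted p = 0.0383). Its median log2 fold change was 0.01 and its mean -0.01. The epithelial adhesion genes EPCAM and CDH1 were at 392 and 91.3 TPM in hiPSC and at 422 and 115 TPM in the organoid; CDH1 rose (0.32, adjusted p = 0.000913) and EPCAM did not pass (adjusted p = 0.190).

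**Figure D1:**
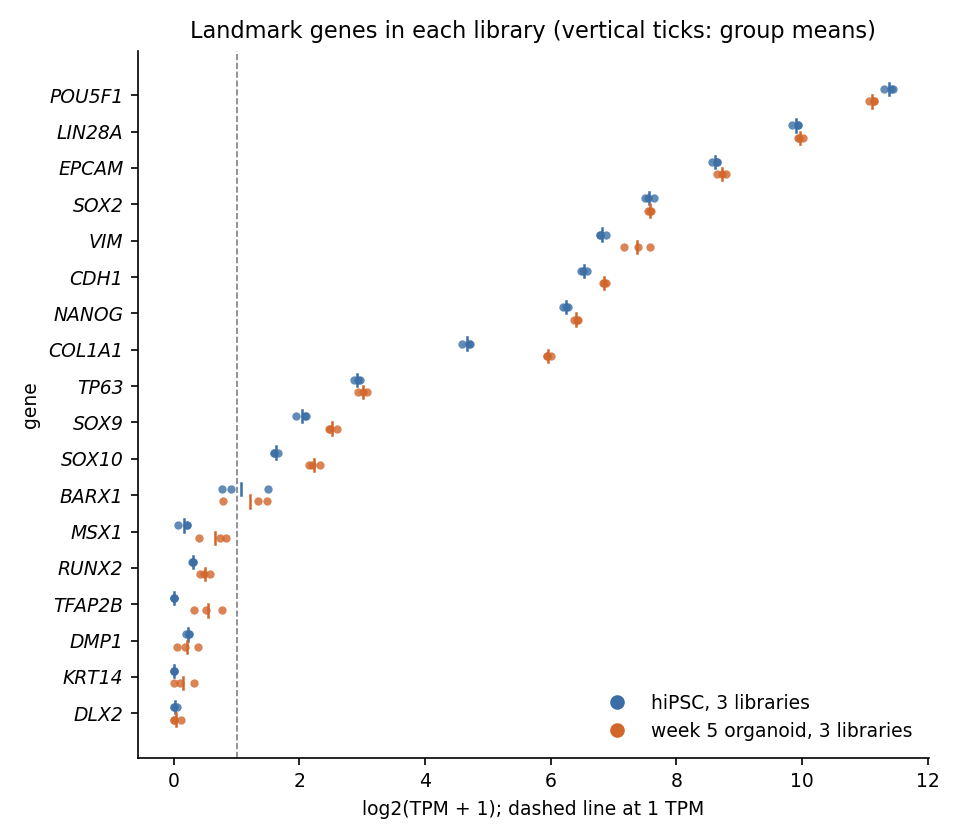
Expression of landmark genes named in the text, as log2(TPM + 1) on the x axis with 1 gene per line; each point is a library, blue for hiPSC and orange for the week 5 organoid (3 each), and vertical ticks are group means. The organoid to hiPSC ratio was 0.827 for POU5F1, 1.04 for LIN28A and 1.01 for SOX2, COL1A1 rose from 24.4 to 61.3 TPM, and MSX1, RUNX2, TFAP2B, DMP1, KRT14 and DLX2 stayed left of the dashed line at 1 TPM.

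Among the landmark genes, MSX1, DLX2, RUNX2, TFAP2B, the basal keratin KRT14 and the dentin matrix gene DMP1 were below 1 TPM in every library and were not tested. MSX1, a transcription factor of dental mesenchyme, had organoid values of 0.32, 0.67 and 0.77 TPM against at most 0.16 TPM in hiPSC. TFAP2B, a neural crest factor, was listed at 0 in all hiPSC libraries and at 0.43, 0.71 and 0.25 TPM in the organoid libraries. TP63, a factor of stratified epithelia, was at 6.58 and 7.07 TPM (adjusted p = 0.416), and BARX1 at 1.14 and 1.35 TPM (adjusted p = 0.615). SOX9 rose from 3.12 ± 0.244 to 4.73 ± 0.303 TPM and SOX10, a neural crest and glial factor, from 2.07 ± 0.0839 to 3.68 ± 0.304 TPM; the SOX9 call was lost after quantile normalization (adjusted p = 0.0876). PAX9, AMBN, AMELX, ENAM and DSPP were not among the 17431 listed genes under these symbols, so no level is given for them. Only 1 of the 17416 genes analysed was at 0 in every library. The deposited list may therefore leave out genes undetected in all 6 libraries, and these genes could be among them, which was not tested.

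In the dental and oral epithelium list, 7 of 12 tested genes rose and 1 fell, led by SOX21 (2.39 to 5.91 TPM) and the activin-binding protein gene FST (5.95 to 10.5 TPM); camera gave an adjusted p of 0.173. In the ameloblast and enamel list 2 of 6 rose, among them TUFT1 (10.3 to 13.7 TPM), a call that quantile normalization removed (adjusted p = 0.0617). FAM83H was at 34.5 and 33.8 TPM, CA2 at 9.77 and 10.1 TPM and RELT at 4.20 and 4.09 TPM (camera adjusted p = 0.696). With limma, 0 of the 4 tested dental mesenchyme genes passed, and 1 had an unadjusted p under 0.05 (PRRX2, at 4.46 and 5.58 TPM). Camera gave that list an adjusted p of 0.741. GLI1 was at 7.57 and 8.54 TPM and BMP4 at 3.34 and 2.77 TPM; BMP4 was lower after both other scalings (log2 fold change -0.32 and -0.49). In the odontoblast and mineralized matrix list 6 of 11 rose, with COL1A1 up from 24.4 ± 1.28 to 61.3 ± 1.81 TPM (log2 fold change 1.30, SE 0.06, adjusted p = 4.71e-08) and COL1A2 from 38.5 to 58.4 TPM; camera gave an adjusted p of 0.134. After the scaling factor 3 of the 11 were higher and 1 lower. In the cranial neural crest list 5 of 13 rose and 2 fell, with NGFR up from 2.2 to 7.48 TPM and ETS1 and FOXD3 down from 20.9 to 15.7 TPM and from 20.3 to 16.5 TPM (camera adjusted p = 0.823; 3 higher and 3 lower after quantile normalization).

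Of 27 HOX genes analysed, regulators of position along the body axis, 7 were tested. Each was listed at 0 in all 3 hiPSC libraries, so it could be tested only by reaching 1 TPM in all 3 organoid libraries, and the rise of all 7 follows from that filter. In organoid replicates 1, 2 and 3, HOXB5 read 7, 7.16 and 1.88 TPM (adjusted p = 6.38e-05) and HOXA4 6.03, 6.15 and 2.48 TPM (adjusted p = 6.47e-06). HOXB2 read 5.06, 5.80 and 2.95 TPM (adjusted p = 9.01e-07) and HOXA5 3.28, 4.19 and 1.28 TPM (adjusted p = 7.17e-05), so that all 4 were lowest in organoid replicate 3. STMN2, a neuronal microtubule regulator, was at most 0.86 TPM in hiPSC and 26.0, 33.5 and 14.8 TPM in organoid replicates 1, 2 and 3 (adjusted p = 1.35e-07). NEFL rose from 9.83 to 21.4 TPM while TUBB3 fell from 168 to 141 TPM, and 9 of 15 tested neuron genes rose and 1 fell. Among stratified epithelium genes 5 of 8 rose and 1 fell (6 and 1 adjusted over the list alone). The rises of KRT13, KRT4 and KRT17 follow from the filter, as does that of STMN2, since none reached 1 TPM in hiPSC. KRT17 was at most 0.92 TPM in hiPSC and 7.16, 10.1 and 3.50 TPM in organoid replicates 1, 2 and 3; PERP rose from 36.9 to 49.0 TPM and SFN fell from 6.22 to 4.73 TPM. Camera called the HOX list (adjusted p = 2.62e-05) and the neuron list (adjusted p = 0.0421) as higher than other genes, and neither with an estimated correlation (adjusted p = 0.665 and 0.706). It did not call the stratified epithelium list (adjusted p = 0.134; 0.0350 after the scaling factor and 0.260 after quantile normalization). The stratified epithelium list was called as higher without organoid replicate 3 (adjusted p = 0.00513) and with no filter (adjusted p = 0.0227). The neuron call was also lost without hiPSC replicate 2 (adjusted p = 0.0579), without organoid replicate 2 (adjusted p = 0.0532) and after GC content and length correction (adjusted p = 0.0716).

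On the deposited TPM most tested extracellular matrix genes rose. In the basement membrane list 16 of 18 tested genes rose and none fell, with the laminin gene LAMA5 up from 20.7 ± 2.43 to 39.4 ± 1.34 TPM and HSPG2, which encodes perlecan, from 9.64 ± 1.34 to 17.1 ± 0.566 TPM (camera adjusted p = 1.16e-05; adjusted p = 0.688 with an estimated correlation). In the fibrillar and interstitial matrix list 16 of 22 rose and none fell (17 and 0 adjusted over the list alone; 11 higher and 1 lower after each of the other scalings); BGN rose from 3.35 to 7.11 TPM and ELN from 3.03 to 6.14 TPM (camera adjusted p = 0.000121; adjusted p = 0.665 with an estimated correlation). Epithelial to mesenchymal transition regulators rose in 8 of 15 cases and fell in 0 (9 and 1 adjusted over the list alone), with LGALS1 up from 19.0 to 47.4 TPM. The intermediate filament gene VIM, a member of that list, rose from 112 ± 4.83 to 166 ± 23.4 TPM (0.56, adjusted p = 0.000439). NOTCH pathway genes rose in 11 of 16 cases and fell in 0 (13 and 0 adjusted over the list alone; 6 and 0 after quantile normalization), with HES4 up from 0.677 to 13.04 TPM and the ligand gene DLL3 from 3.47 to 7.86 TPM. Camera called both lists as higher (adjusted p = 0.0109 and 0.00282), and neither with an estimated correlation (adjusted p = 0.665 for each). Low genes rose more than abundant ones, and none of these lists was compared with genes of equal level. The share of level in these camera calls is therefore unknown.

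Stress and dissociation response genes had the lowest adjusted p of the 34 lists. Of 21 tested, 15 rose and 1 fell (camera adjusted p = 8.33e-07; adjusted p = 0.559 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 6.91 ± 1.08 to 46.0 ± 3.99 TPM, and the immediate early gene EGR1 from 4.36 ± 0.0808 to 27.8 ± 0.304 TPM (log2 fold change 2.42, SE 0.07). HSPA5, a chaperone of the endoplasmic reticulum, fell from 426 ± 19.8 to 327 ± 16.4 TPM. Cell cycle genes were lower than other genes as a list (camera adjusted p = 1.96e-06; adjusted p = 0.665 with an estimated correlation), although 23 of 31 did not pass, 7 fell and 1 rose. After the scaling factor 23 fell and 0 rose, and after quantile normalization 12 fell and 1 rose. PCNA fell from 455 to 362 TPM and RRM2 from 99.4 to 73.1 TPM, whereas CCNB2 rose from 147 to 167 TPM on the deposited TPM. Ribosomal protein genes were also lower as a list (camera adjusted p = 4.42e-05; adjusted p = 0.665 with an estimated correlation), with 7 of 34 lower and 1 higher, and 0 and 0 adjusted over the list alone. After the scaling factor 15 were lower and 0 higher, and after quantile normalization 1 was lower and 1 higher. RPS15 fell from 3854 to 3134 TPM and RPL23 from 554 to 452 TPM, and RPS19 rose from 1565 to 1761 TPM. The ribosomal call ended after quantile normalization, where camera found no difference from other genes (adjusted p = 0.986). The median log2 fold change of tested genes fell with level, from 0.26 in the lowest eighth to -0.01 in the highest. Camera compares a list with all other tested genes, so a list of abundant genes can come out lower through its level alone. In the same way a list of low genes can come out higher. Median hiPSC levels were 3139 TPM for ribosomal protein, 119 for cell cycle, 278 for oxidative phosphorylation and 89.4 for pluripotency genes. Among the 7 lists called as higher they ran from 0 TPM for HOX to 18.2 TPM for stress response genes. They were 3.25 TPM for fibrillar and interstitial matrix and 5.75 TPM for NOTCH pathway genes. No list was compared with genes of equal level.

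**Figure D2:**
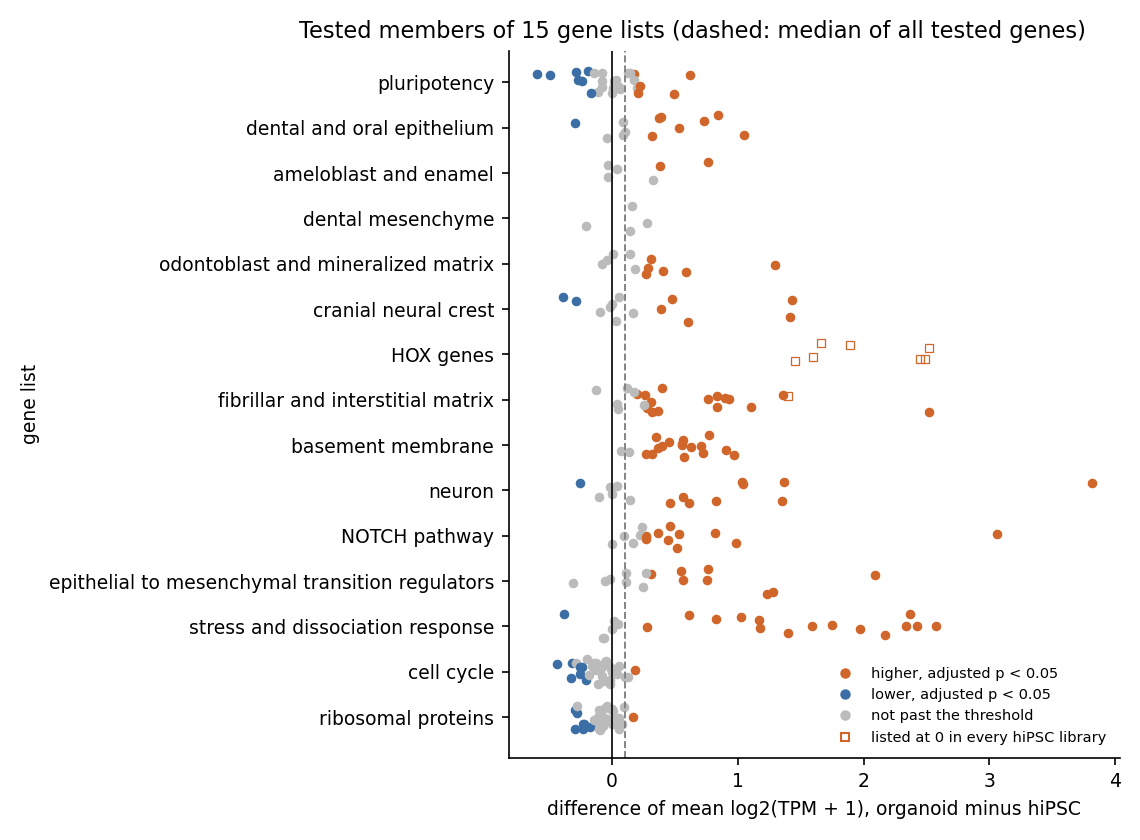
Change of each tested member of 15 gene lists, as organoid minus hiPSC difference of mean log2(TPM + 1) on the x axis; orange and blue points passed the limma threshold as higher or lower, grey points did not, and open squares were listed at 0 in every hiPSC library. The dashed line is the median of all tested genes (0.11), which scaling moves to -0.03. HOX, matrix and stress genes extend to the right, while cell cycle and ribosomal protein genes lie mostly left of it. After quantile normalization camera did not call the ribosomal protein list (adjusted p = 0.986).

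The other lists were not called by camera on the deposited TPM. Glycolysis and hypoxia genes rose in 10 of 24 cases and fell in 2 (adjusted p = 0.359). After the scaling factor 8 were higher and 6 lower (adjusted p = 0.394), and after quantile normalization 10 were higher and 4 lower (adjusted p = 0.0444). VEGFA, the vascular growth factor, rose from 19.2 to 63.3 TPM and P4HA1 from 15.5 to 26.2 TPM, while LDHA fell from 568 to 473 TPM and HK2 from 42.2 to 36.0 TPM. Antigen presentation and interferon genes rose in 11 of 21 cases (adjusted p = 0.305; 6 higher and 3 lower after the scaling factor), among them BST2 (64.0 to 118 TPM) and PSMB9 (3.07 to 7.67 TPM). Hedgehog and FGF targets rose in 6 of 14 cases and fell in 1 (6 and 2 adjusted over the list alone; adjusted p = 0.427); after the scaling factor 3 were higher and 2 lower, and after quantile normalization 2 and 3. SPRY4 rose from 30.7 to 49.1 TPM and IL17RD fell from 20.1 to 15.6 TPM. BMP targets rose in 4 of 10 cases (5 adjusted over the list alone; adjusted p = 0.394), with ID4 up from 2.38 to 6.15 TPM. Of 9 tested WNT targets 2 rose (1 adjusted over the list alone; adjusted p = 0.696), and the 4 most abundant did not pass. After the scaling factor 1 was higher and 1 lower, and after quantile normalization 0 were higher and 3 lower, among them TCF7 (adjusted p = 0.0465). CCND1 was at 43.7 and 44.5 TPM, AXIN2 at 11.6 and 12.5 TPM, ZNRF3 at 7.6 and 7.77 TPM and TCF7 at 7.32 and 7.24 TPM. Oxidative phosphorylation genes mostly did not pass, with 2 of 26 higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.119), but 0 were higher and 9 lower after the scaling factor (adjusted p = 0.0312). After quantile normalization 3 were higher and 2 lower (adjusted p = 0.698). The list was called as lower without hiPSC replicate 3 (adjusted p = 0.0405) and without organoid replicate 3 (adjusted p = 0.00590). NDUFA2 fell from 209 to 153 TPM, while NDUFV1 rose from 158 to 182 TPM.

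Among markers of other cell types, 9 of 23 tested simple epithelium genes rose, including PRSS8 (88.0 to 142 TPM) and ELF3 (4.48 to 7.65 TPM). Camera gave that list an adjusted p of 0.298. After quantile normalization it was 0.0408, with 7 members higher and 2 lower, and after the scaling factor 0.530, with 5 higher and 3 lower. Glia and Schwann cell genes rose in 7 of 12 cases and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.249), with 4 higher and 2 lower after quantile normalization. L1CAM was up from 17.9 to 29.7 TPM, GAP43 up from 17.95 to 25.3 TPM and SLC1A3 down from 14.9 to 10.6 TPM. Neural progenitor genes went both ways, 3 of 8 higher and 2 lower (adjusted p = 0.696; 2 higher and 3 lower after the scaling factor, 0 and 2 after quantile normalization). SOX11 rose from 5.41 to 7.23 TPM and NES from 66.8 to 77.1 TPM, while OTX2 fell from 38.2 to 33.1 TPM and SOX3 from 20.9 to 15.95 TPM. Smooth muscle and pericyte genes rose in 6 of 14 cases and fell in 2 (adjusted p = 0.741; 5 higher and 4 lower after the scaling factor, 4 and 2 after quantile normalization). ACTA2 rose from 1.90 to 7.91 TPM and MCAM from 13.2 to 20.01 TPM, RGS5 fell from 11.8 to 8.10 TPM and TPM2 from 350.4 to 301 TPM. Skeletal and cardiac muscle genes rose in 2 of 8 cases and fell in 1 (adjusted p = 0.696), but 1 was higher and 3 lower after each of the other scalings. ACTA1 was up from 2.64 to 6.02 TPM, ACTC1 down from 52.0 to 42.3 TPM and RYR1 up from 3.98 to 5.16 TPM. Cartilage genes rose in 4 of 10 cases (adjusted p = 0.459; 1 higher and 2 lower after quantile normalization), with CNMD up from 150.4 to 169.7 TPM and COL9A3 from 60.5 to 68.6 TPM. Endothelium genes rose in 2 of 7 cases and fell in 2 (3 and 2 adjusted over the list alone; adjusted p = 0.696), with 1 higher and 2 lower after each of the other scalings. ERG was down from 4.06 to 2.94 TPM, EGFL7 up from 39.2 to 45.5 TPM, FLT1 at 31.7 and 36.2 TPM and KDR at 23.7 and 25.3 TPM.

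Trophoblast and amnion genes rose in 3 of 7 cases (4 adjusted over the list alone; adjusted p = 0.305), among them IGFBP3 (4.84 to 11.2 TPM) and GABRP (2.69 to 4.30 TPM), with BAMBI at 17.6 and 20.7 TPM. Of 4 tested endoderm and liver genes 2 rose and 1 fell (adjusted p = 0.540). Both rises, of CXCR4 and TTR, follow from the filter, since neither gene reached 1 TPM in hiPSC. CXCR4 rose from 0.837 to 4.05 TPM and AFP fell from 1.66 to 0.937 TPM; FOXA3 was at 29.2 and 31.5 TPM. TTR, which encodes transthyretin, was listed at 0 in hiPSC and at 1.40, 3.98 and 5.01 TPM in organoid replicates 1, 2 and 3 (adjusted p = 7.82e-05). Blood and macrophage genes rose in 2 of 4 cases (3 adjusted over the list alone; adjusted p = 0.298). AIF1 rose from 24.8 to 31.0 TPM and CD68 from 0.820 to 1.82 TPM, and both calls were lost after quantile normalization (adjusted p = 0.0893 and 0.0998). HBA2, which has a near-identical copy, was at 0.00, 0.29 and 1.79 TPM in hiPSC and 1.28, 1.51 and 1.72 TPM in the organoid, and FCER1G at 1.36, 0.00 and 0.00 TPM and 1.22, 0.58 and 1.36 TPM. In the eye and lens list 1 of 5 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.823). CRYGD was down from 12.9 to 8.51 TPM, CRYBB1 at 6.11 and 7.70 TPM, CRYAB at 1.47 and 2.43 TPM and CRYBB2 at 1.57 and 1.73 TPM. With limma 0 of 4 melanocyte genes passed, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.298). PMEL was at 78.9 and 81.2 TPM, EDNRB at 17.5 and 16.3 TPM, KIT at 9.02 and 8.21 TPM and RAB27A at 4.10 and 4.18 TPM. After the scaling factor 2 of these 4 were lower, and 3 after quantile normalization.

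Most genes that were near 0 in hiPSC and higher in the organoid had their lowest organoid value in replicate 3. The set, defined after the values were seen, held the 38 genes with an hiPSC mean under 0.5 TPM, an organoid mean of at least 2 TPM and an adjusted p under 0.05. Its summed expression was 181, 215 and 109 TPM in organoid replicates 1, 2 and 3 against 6 to 7.89 TPM in hiPSC. Of the 38 genes, 31 (81.6%) were lower in replicate 3 than in both other organoid libraries, compared with 53.7% of all tested genes and 6 of the 15 stress list genes that rose. S100A9, a calprotectin subunit, was listed at 0 in hiPSC and at 23.0, 27.6 and 1.72 TPM in organoid replicates 1, 2 and 3 (adjusted p = 0.000988). KRT13 was listed at 0 in hiPSC and at 5.67, 7.07 and 2.20 TPM in the organoid (adjusted p = 2.00e-05), and COL3A1 was at most 0.03 TPM in hiPSC and at 5.44, 5.81 and 3.50 TPM in the organoid. LTB (7.97, 7.20 and 8.24 TPM) and TTR were not lowest in replicate 3. Among the 17416 genes analysed, 0 had an hiPSC mean of at least 2 TPM and an organoid mean under 0.5 TPM, against 43 in the opposite direction whatever their p.

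**Figure D3:**
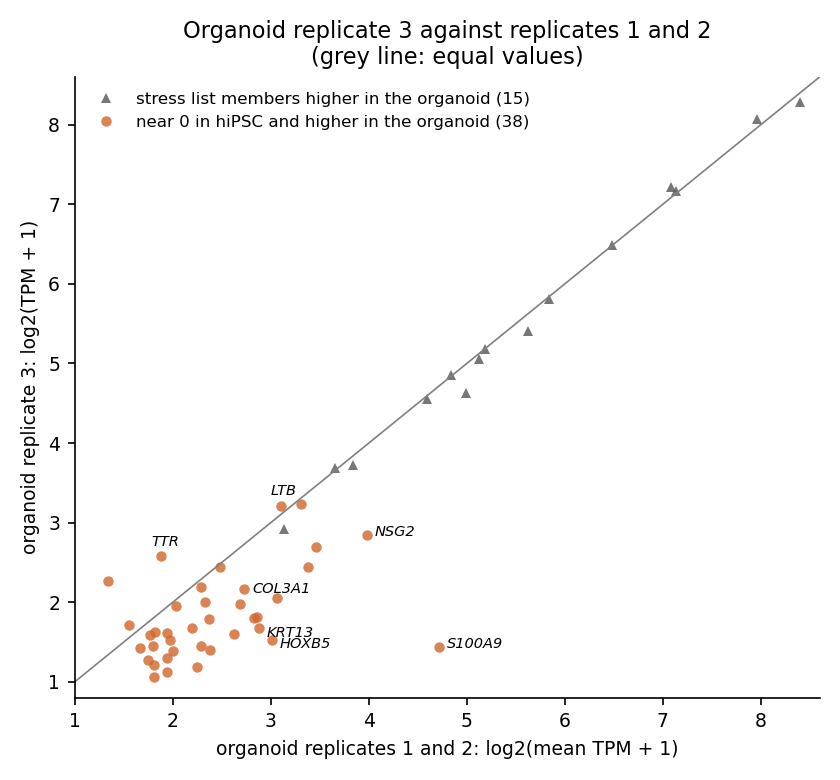
Organoid replicate 3 (y axis, log2(TPM + 1)) against the mean of organoid replicates 1 and 2 (x axis, log2(mean TPM + 1)); orange circles are the 38 genes near 0 in hiPSC and higher in the organoid, and grey triangles the 15 stress list genes that rose. The triangles lie near the grey line of equal values, while 31 of the 38 circles were lower in replicate 3 than in both other libraries.

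With an estimated correlation none of the 34 lists was called (adjusted p between 0.559 and 0.90), against 9 with the preset correlation and 25, all higher, with fry, which does not compare a list with other genes. Camera called 8 lists in the same direction under all 3 scalings. The dental mesenchyme, neural progenitor, muscle, endothelium and WNT lists had a median and a mean above 0 but stood lower than other genes in camera, and oxidative phosphorylation had a median of 0.003 and a mean of -0.006. For the 19 lists with no count adjusted over the list alone given above, that count was the same as over all genes. Among the named genes, the calls of NANOG, NES, CNMD, COL9A3, EGFL7, RYR1 and AIF1 were lost after both other scalings, those of CCNB2, NDUFV1 and RPS19 after the scaling factor, and those of SOX9, TUFT1, SOX11, CD68, GABRP, RPS15 and RPL23 after quantile normalization. Of the 101 named genes that passed the threshold, 17 did not pass in at least 1 fit that left out a library (adjusted p between 0.0505 and 0.164), and removing any of the 6 libraries ended at least 1 of these calls. They included NANOG, FOXD3, SFN, NES, OTX2, CNMD, HK2, RPS15, RPS19, RPL23, TPM2, COL9A3, EGFL7, CCNB2, NDUFV1 and RYR1, none with a log2 fold change beyond 0.32 in size.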

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

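The GC content and length correction and the scaling factor for list tests were chosen after seeing the data. The number of changed genes stayed within 1.5 times of 4869 in every alternative except a fold change of 2 tested in the model (90 changed, 90 higher and 0 lower, the same for the 2-fold count). Quantile normalization gave 2085 higher and 2432 lower genes, and 168 changed 2-fold (148 higher and 20 lower); the scaling factor gave 2436 higher and 2810 lower, with 6 lower 2-fold. These scalings remove the median shift by construction. Array weights gave 1632 lower genes, and 5 lower 2-fold. A pseudocount of 0.1 gave 545 genes changed 2-fold (533 higher and 12 lower) and a pseudocount of 0.01 gave 599 (585 higher and 14 lower), since low genes then have larger folds. The stricter filter left 155 changed 2-fold, 155 higher and 0 lower. With no filter, and with the GC content and length correction, 0 were lower 2-fold; the cause was not tested.

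Leaving out 1 library, with the filter at 1 TPM in as many libraries as the smaller group, gave 3621 to 4730 changed genes and 525 to 811 lower ones (536 without hiPSC replicate 3 and 525 without organoid replicate 2). The lower 2-fold count ran from 0 to 4 (4 without hiPSC replicate 2, 0 without organoid replicate 1, 2 without organoid replicate 3), and 8 to 12 lists were called. With an estimated correlation 0 of the 34 lists were called. Fry called 25 of the 34, but not the cell cycle (adjusted p = 0.0739) and ribosomal protein lists (adjusted p = 0.202), which camera had called. The muscle list, lower in camera without a call (adjusted p = 0.696), was higher in fry (adjusted p = 0.0443). With quantile normalization the camera direction of the ribosomal protein list changed sign, but the list was not called (adjusted p = 0.986). RAB27A changed sign with quantile normalization (log2 fold change -0.25, adjusted p = 0.0490). The difference in spread between the groups was -0.000887 with a pseudocount of 0.1, and the cause of these sign changes was not tested.

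With the replicate number as a block, 4014 genes changed (3376 higher and 638 lower), 3982 of them shared with the fit without it, 273 changed 2-fold and 9 lists were called. The main fit had no block, a choice fixed before the data were examined, because no label says that equal numbers share a culture. Libraries of the same number had correlations of deviations of -0.279, 0.0621 and -0.191. No hiPSC library correlated best with the organoid library of its own number. Among the organoid libraries, only replicate 2 correlated best with the hiPSC library of its own number. Over all alternatives, named genes kept their side of the threshold in 1939 gene settings (in 41 of these the sign changed with neither fit past the threshold), lost a call in 200, gained a call in 29 and reversed in 1. TPM keeps no depth, so counting error could not be separated from the spread of libraries.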

Other observations

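The 5 gene lists described first, the set of genes near 0 in hiPSC, and the tests of scaling in replicate 3, of differentiated RNA in replicate 3, of exchanged libraries, of mixed RNA and of the share of TPM taken by abundant genes were all chosen after the result was seen.

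Cholesterol synthesis and uptake genes fell together, with 19 of 25 lower and 0 higher, and 22 lower after each of the other scalings. INSIG1, a sterol-responsive regulator, fell from 39.5 ± 1.77 to 24.1 ± 2.18 TPM (n = 3, limma adjusted p = 3.17e-05) and SQLE from 112 to 79.3 TPM. Genes of amino acid supply and the integrated stress response rose in 23 of 24 cases. TRIB3 rose from 16.4 ± 1.51 to 88.6 ± 1.00 TPM, DDIT3 from 7.14 to 35.4 TPM, ASNS, which encodes asparagine synthetase, from 146 to 328 TPM and PSAT1, an enzyme of serine synthesis, from 398 to 682 TPM. ATF4 itself fell from 779 to 693 TPM, a call lost after quantile normalization (adjusted p = 0.306). All 8 tested metallothionein genes rose, with MT1X up from 88.4 to 459.9 TPM. With an estimated correlation in camera these 3 lists had adjusted p values of 0.0224, 0.0174 and 0.0101. The adjustment was over 5 lists, which is milder than over the 34 lists above. These 5 lists were picked because their genes moved and so are not independent evidence.

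Genes regulated by p53 rose in 15 of 20 cases and fell in 2 (adjusted p = 0.0794 with an estimated correlation). MDM2 rose from 18.2 to 28.5 TPM, while BAX fell from 422 to 325.5 TPM and RRM2B from 30.4 to 22.8 TPM. Replication-dependent histone genes went both ways, with 13 of 37 higher and 4 lower (camera adjusted p = 0.968), and 10 and 10 after quantile normalization. Their near-identical copies and lack of poly(A) tails make their values in poly(A)-selected libraries uncertain.

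The genes near 0 in hiPSC and higher in the organoid had a median of 0.576 times the level of the other organoid libraries in replicate 3 (log2 ratio -0.80), and 81.6% were lower there than in both others. Scaling of replicate 3 is argued against by the median log2 ratio over all tested genes, -0.0704, and a bias of GC content, length or level by that of matched genes, -0.0480. A smaller amount of RNA from differentiated cells in replicate 3 stays open, since the share of 81.6% is the pattern itself and gives no support to it. No batch is given in the labels, so a difference in culture or handling of replicate 3 stays open and untested.

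Pluripotency genes stayed near the hiPSC level in the organoid, with a median TPM ratio of 1.01 over 28 genes, from 0.638 for LEFTY2 to 1.59 for UTF1. An exchange of part of the libraries between the groups is argued against because 0 of 6 libraries lay nearer a library of the other group than their own farthest replicate. An exchange of the whole groups would leave these distances as they are, so it stays open here. The 27 analysed HOX genes summed to 0.13 to 0.22 TPM in libraries labelled hiPSC and to 15.48 to 43.09 TPM in organoid libraries. These sums speak against such an exchange without excluding it. Unchanged hiPSC RNA mixed with RNA of cells without these genes would lower all of them by the same ratio. Of the 28, 17 had a log2 fold change over 2 SE from the list's median. That SE comes from the spread of these libraries, which may be technical, and the rises and falls in the list were known when this test was chosen. Among all tested genes 37.4% changed, so the test speaks only to hiPSC RNA without any change. A mixture that holds slightly changed hiPSC, or cells that express part of the list, stays open. Bulk TPM does not separate a change in all cells from a mixture of changed cells, so the state of the cells stays open. An exchange with a sample outside the series was not tested and stays open.

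Low genes were higher in the organoid, with a median log2 fold change of 0.26 in the lowest eighth of genes by level and -0.01 in the highest. A single shift of all genes from the share of TPM taken by abundant genes is argued against by the difference of 0.27 between these eighths, and GC content and length by the 0.27 left after their correction. Background along the genome was examined with 92 receptor and keratin-associated genes that are silent in most tissues. Their summed TPM was 1.12 times as high in the organoid. The groups overlapped through hiPSC replicate 1 only (17.74 TPM, against 16.45 to 17.83 in the organoid), so this ratio alone does not decide. Their mean rise was 0.0203 TPM per gene, against a median rise of 0.477 TPM in the lowest eighth. This argues against a background as large as that rise, and a smaller one stays open. An effect of a wider range of cell types in the organoid was not tested and stays open.

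The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 4869 changed genes, 273 changed 2-fold and 9 lists, and the highest of the other splits gave 0, 0 and 7. As large a result came from 1 split each time, the real one. Every other split mixes hiPSC and organoid libraries in each group, so their difference enters the spread within groups and lowers the gene calls. These splits therefore do not show how many genes chance alone would call.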
